A study of Mus musculus with 7 samples.

How the data were processed

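Bulk RNA sequencing was done on oligodendroglia taken from mouse brain, in 2 groups of cells. The control group of 3 libraries was wild type for Sox9, and the Sox9-tg group of 4 libraries overexpressed it. Groups and replicate numbers were taken from the sample titles, which call the libraries biological replicates. Nothing in the labels says whether these came from separate animals, litters or cultures, so p-values measure the spread between these samples, which may in part be technical. The labels give no sex, age in days, sorting step or batch. The log2 ratio of Xist to Y-linked levels differed widely between libraries, from -1.78 to 2.47 in control and from -2.22 to 3.83 in Sox9-tg libraries.

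The authors deposited a table of whole-number read counts per gene for each library, with an Ensembl gene ID and a gene name on each row. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2, DESeq2 and DESeq were used with the mouse build GRCm38. Their roles, order and settings, the annotation release, the treatment of reads with several matches and the use of strand are not given in the sources used here. The deposited counts were raw: they were whole numbers, and their totals differed between libraries. Reads of overlapping genes, of a gene and its antisense partner, and of near-identical copies such as histone and globin genes therefore cannot be told apart with certainty. Counts per gene cannot separate transcripts of the transgene from those of the endogenous Sox9 gene. Gene coordinates, GC content and transcript lengths were taken from GENCODE mouse release M21, which uses GRCm38, and 49056 of the 49315 gene IDs had a coordinate in it.

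Genes with low counts were removed with edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 16616 genes. Between 0.08% and 0.36% of each library's counts fell in removed genes. Libraries were scaled with TMM factors (0.965 to 1.05), and levels in CPM were computed with edgeR's cpm function on the scaled library totals. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 16616 genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. A total of 3 counts in a library corresponded to 0.0983 to 0.19 CPM, and the biological coefficient of variation was 0.265.

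A set of 33 gene lists from textbook knowledge was fixed before the data were examined. The lists covered the oligodendrocyte lineage, other cell types a preparation could hold, cartilage genes, the Sox family, glial transcription factors, cell cycle, signalling, matrix, metabolism, stress and RNA quality. Some genes belonged to several lists, at most 5 shared by a pair among those tested. Each list was tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. Beside it stand the number of members past the gene threshold over all genes, the number past it when adjusted over the list alone, and the list's median log2 fold change. With an estimated correlation per list, 0 of the 33 lists passed the threshold, with 3 at an unadjusted p under 0.05, and the adjusted p is given beside each call. The rotation test fry, which asks whether a list's genes move on balance in a single direction, called 12 lists.

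The genes named were chosen by a rule fixed together with the lists: Sox9, the 12 largest changes in each direction with adjusted p under 0.05, a mean of at least 5 CPM in a group and no overlap between groups (predicted genes, clone names and sex-linked genes left out), the 5 smallest adjusted p in each direction, up to 4 members of each list with the smallest p, all Sox family members tested, and 12 identity genes. The rule gave 168 genes. A further 46 genes were named outside the rule, after their values were seen: list members named because few were called in their direction (Megf11, Anln, Slc1a2, Ntsr2, Glul, Gja1, F3, Tspan12, Ddah1, Tnc, Ngfr, Mfng, Notum, Bmpr1b, Id2, Id3, Bmp7, Ltbp1, Gas1, Il17rd, Dusp4, Fbln2, Eln and Col5a2), Mog, Tnr and Dlx1, and genes given only under other observations. They were put through the same alternatives, unlike Slc17a7 and Neurog2, which are given only as list members that did not pass. Some genes that the rule gave are not reported here by name.

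The steps were tested on simulated counts for the 16616 genes of this comparison, with 200 genes changed by known folds. The test recovered 13.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 83.3% of those changed 4-fold, and 6.6% of its calls were false. In a second simulation camera called 0 of 100 unchanged lists and all 5 shifted lists of 25 genes. These simulated genes varied independently, so the list result does not cover genes that vary together.

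Alternatives covered other scalings, filters, thresholds and tests (DESeq2 1.42.0, limma-voom with and without library weights, glmTreat), each library left out in turn, a term for the ratio of Xist to Y-linked counts, the replicate number as a block, and other list tests. A further 3 were chosen after seeing the data: leaving out both libraries numbered 2, a correction for GC content and transcript length, and removal of mitochondrial genes and of 2 genes that overlap ribosomal RNA repeats, Gm42418 and Gm23935. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom within a group was 4.93. That value was for Sox9-tg replicates 3 and 4, which were far closer than the other pairs within a group (39.4 to 78.4).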

Results

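Oligodendroglia from mouse brain were compared between wild-type cells (control, 3 libraries) and cells that overexpressed the transcription factor Sox9 (Sox9-tg, 4 libraries). The series' title places the cells among NG2 glia of the early postnatal period, the dividing progenitors from which oligodendrocytes form, and sets the question of which genes respond to Sox9 in them. Control libraries 1 to 3 held 17275678, 29379986 and 30507326 gene counts. Sox9-tg libraries 1 to 4 held 19045591, 20815459, 15768472 and 20771299. Values after a ± sign are SD over the 3 control or 4 Sox9-tg libraries, log2 fold changes are Sox9-tg minus control, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

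Sox9 (ENSMUSG00000000567, GRCm38 chromosome 11, 112782224 to 112787760, plus strand), which directs cartilage formation and the switch of neural progenitors to gliogenesis, rose 9.88-fold. Its level was 295 ± 57.0 CPM in control and 2915 ± 588 CPM in Sox9-tg libraries (log2 fold change 3.31, SE 0.24, adjusted p = 0.000181). All 7 libraries matched their labels in this gene, the lowest Sox9-tg library (replicate 1) holding 2207 CPM and the highest control library (replicate 2) 353 CPM.

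Across the transcriptome, 14 of 18 tested cartilage genes and 20 of 25 NG2 glia genes rose with Sox9. Falls were seen for 32 of 35 DNA replication genes and 29 of 31 mitosis genes. They were also seen for 5 of 12 Hedgehog pathway, 8 of 20 radial glia and 8 of 27 tested neuronal genes. Camera called these lists, each with an adjusted p = 0.36 with an estimated correlation. Of 16616 genes tested, 2251 changed, 1278 higher and 973 lower in Sox9-tg libraries. The excess of higher genes depended on the scaling, with 1113 higher and 1112 lower under upper-quartile factors and 1117 and 1087 under total counts. At least 2-fold changes were found for 745 of the higher and 547 of the lower genes, and log2 fold changes beyond 3 for 118 higher and 15 lower genes. The groups did not overlap for 24.5% of tested genes, against 5.71% by chance for 3 against 4 libraries. Among the genes eligible for naming by size, the largest rises were those of Foxd3, a neural crest transcription factor (0.551 ± 0.604 to 50.7 ± 20.03 CPM, log2 fold change 6.35, SE 0.68), Cnmd, the cartilage protein chondromodulin (6.02, SE 0.76), Tbx2 (5.61, SE 0.45), Enpp6, a marker of newly forming oligodendrocytes (5.35, SE 0.79), and Erbb3, a neuregulin receptor (5.19, SE 0.31). Gjc3, Susd5, Col6a3, Col2a1, Mag, Col9a1 and Matn1 completed the 12 largest, with log2 fold changes from 5.19 to 4.98. Col6a3 varied widely between Sox9-tg libraries (110 ± 116 CPM). Single libraries moved several of these values, and with them the order: the log2 fold change of Foxd3 was 7.48 without control replicate 3, the log2 fold change of Cnmd 6.86 without control replicate 2 and 5.39 without Sox9-tg replicate 2, the log2 fold change of Matn1 5.58 without control replicate 3 and 4.12 without Sox9-tg replicate 2, and the log2 fold change of Col6a3 4.00 without Sox9-tg replicate 2.

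Among genes eligible by the same limits on level and overlap, the largest falls were those of Dll4, a Notch ligand (20.4 ± 4.04 to 1.69 ± 0.272 CPM, log2 fold change -3.58, SE 0.21), the adenosine receptor gene Adora2a (-3.46, SE 0.32) and the serotonin receptor gene Htr3a (-3.46, SE 0.33). Clec3b, Upp1, Aldh1a3, Gipr, Eomes, Gli1, Ndst3, Mical2 and Drd2 followed, with log2 fold changes from -3.21 to -2.60. Without control replicate 1, the log2 fold change of Aldh1a3 was -1.92 and no longer passed (adjusted p = 0.0557). Among genes with a symbol other than a clone name, those with the smallest adjusted p, 0.000118, included Dct, Sntb1, Adgrg6 and Shc4, which rose, and Mdga1, Gli2 and Nbl1, which fell. Gria1, a glutamate receptor subunit, fell from 57.9 ± 9.56 to 11.04 ± 1.58 CPM (adjusted p = 0.000141). The number of changed genes moved when 1 library was left out. It was 1261, 2045 and 965 without control replicates 1, 2 and 3. Without Sox9-tg replicates 1 to 4 it was 3169, 1900, 1342 and 1356. Of the 965 calls without control replicate 3, 960 were also calls with all libraries. Fewer libraries lower the power of the test, so a smaller count or a lost call need not mark that library as unusual.

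**Figure D1:**
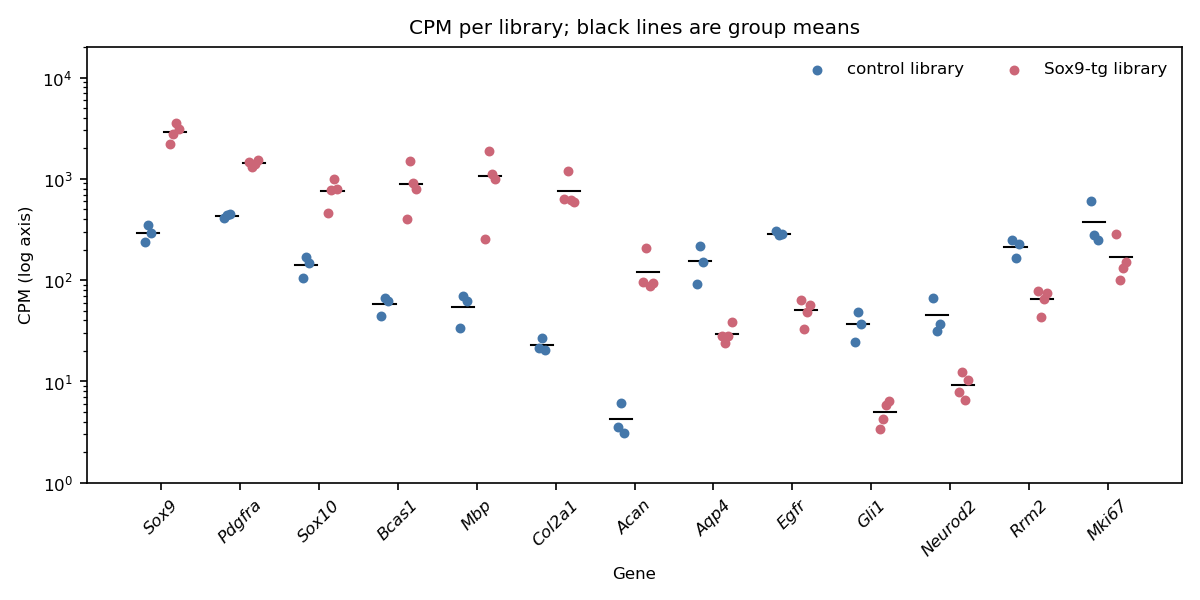
CPM per library (log axis) of 13 genes, with control libraries in blue, Sox9-tg libraries in red and group means as black lines. Sox9 lay between 2207 and 3597 CPM in Sox9-tg libraries and between 239 and 353 CPM in control libraries, and Mki67 was the only gene of the 13 whose groups overlapped.

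Most markers of NG2 glia rose. Of 25 listed genes, all tested, 20 rose and 1 fell (adjusted over the list alone, 21 rose and 2 fell), with a median log2 fold change of 1.57. Pdgfra, the PDGF receptor that defines these cells, rose from 433 ± 22.6 to 1432 ± 100.8 CPM (log2 fold change 1.72, SE 0.14), and Cspg4, which encodes NG2 itself, rose from 114 ± 17.9 to 593 ± 93.2 CPM (2.38, SE 0.19). Matn4 (4.48, SE 0.31) and Sox6 (1.83, SE 0.17) rose as well, and Olig2 rose from 338 ± 41.4 to 664 ± 116 CPM, a call that was lost without control replicate 3 (adjusted p = 0.0605). The member that fell was Megf11, with a log2 fold change of -0.61, and its call was lost without control replicate 2 (adjusted p = 0.0542), control replicate 3 (0.0545) or Sox9-tg replicate 3 (0.0519). The list's camera adjusted p was 2.46e-18 (adjusted p = 0.36 with an estimated correlation). Sox9-tg replicate 1 stood below the other Sox9-tg libraries in this list, at a mean log2 CPM of 8.34 against 8.68 to 8.73, with control libraries at 6.72 to 7.18.

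Genes of later stages of the lineage also rose, though not evenly. Of 18 tested genes of committed progenitors and premyelinating oligodendrocytes, 14 rose and none fell (adjusted over the list alone, 15 and 0), with a median log2 fold change of 2.06. Bcas1 rose from 57.9 ± 12.2 to 896 ± 448 CPM, and Zfp488, Itpr2 and Mpzl1 had log2 fold changes of 2.64, 2.61 and 1.56. Camera gave that list an adjusted p of 4.46e-10 (adjusted p = 0.36 with an estimated correlation). Of 26 tested myelin and mature oligodendrocyte genes, 14 rose, 1 fell and 11 did not pass (adjusted over the list alone, 15 and 1), with a median of 1.72. Myrf, the transcription factor required for myelination, rose from 7.97 ± 4.33 to 182 ± 97.3 CPM. Mbp, which encodes myelin basic protein, rose 19.3-fold, from 54.9 ± 18.8 to 1063 ± 665 CPM. Mog, which encodes a protein of the outer myelin surface, did not pass, at 4.77 ± 1.15 CPM in control and 3.56 ± 0.586 CPM in Sox9-tg libraries. The member that fell was Anln (-0.87), also a cytokinesis gene, whose call was lost without control replicate 1 (adjusted p = 0.0648), control replicate 3 (0.0754) or Sox9-tg replicates 3 or 4 (0.0609 each). The myelin list's camera adjusted p was 1.82e-07 (adjusted p = 0.36 with an estimated correlation). Sox9-tg replicate 1 stood below the other Sox9-tg libraries in this list, at a mean log2 CPM of 4.28 against 5 to 5.4, with control libraries at 2.62 to 3.53.

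Cartilage genes, many of them known SOX9 targets in chondrocytes, rose most. Of 25 listed genes, 18 were tested, of which 14 rose and none fell (adjusted over the list alone, 14 and 0). The median log2 fold change of those tested was 2.83. Col2a1, the main collagen of cartilage, rose from 22.99 ± 3.48 to 758 ± 290 CPM (5.04, SE 0.33, adjusted p = 0.000119). Col9a1 rose from 6.92 ± 1.57 to 227 ± 112 CPM, Col9a3 from 86.1 ± 17.01 to 962 ± 284 CPM, and Acan, which encodes aggrecan, from 4.24 ± 1.64 to 121 ± 57.1 CPM. Matn1 lost its call with limma-voom (adjusted p = 0.0923), and Sox5 did not pass without control replicate 3 (adjusted p = 0.0707). The camera adjusted p was 7.3e-13 (adjusted p = 0.36 with an estimated correlation).

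Chondroitin sulphate proteoglycans and tenascins followed the same direction, with 9 of 21 tested members higher and 1 lower (adjusted over the list alone, 12 and 1), a median of 0.60 and a camera adjusted p of 7.56e-07 (adjusted p = 0.36 with an estimated correlation). The sulphotransferase gene Chst11 and the xylosyltransferase gene Xylt1 rose by log2 fold changes of 1.75 and 1.60. Tnr rose from 122 ± 17.6 to 1263 ± 682 CPM, whereas Tnc, a tenascin of neural progenitors, fell from 931 ± 249 to 306 ± 64.8 CPM. Other matrix genes went both ways: of 33 collagen, laminin and related genes, 8 rose, among them Lama4 and Lamc1, and 4 fell, Lama5, Fbln2, Eln and Col5a2 (adjusted over the list alone, 9 and 5). Without control replicate 3 the last 3 had adjusted p = 0.0885, 0.154 and 0.168, without control replicate 1 0.0712, 0.135 and 0.186, and without control replicate 2 0.0684, 0.105 and 0.11. Eln and Col5a2 were also lost without Sox9-tg replicates 2 (0.0787 and 0.0985), 3 (0.0818 and 0.128) or 4 (0.0913 and 0.0669), and Col5a2 without Sox9-tg replicate 1 (0.0569). That list's median was -0.26, or 0.25 without control replicate 2, while its mean was 0.22, and camera did not call it (adjusted p = 0.613).

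Almost all cell-cycle genes fell. Of 35 DNA replication genes, 32 fell and none rose (adjusted over the list alone, 35 and 0), with a median log2 fold change of -0.87. The ribonucleotide reductase gene Rrm2 fell from 214 ± 44.0 to 65.2 ± 15.8 CPM (-1.71, SE 0.22) and Pcna from 245 ± 29.9 to 124 ± 14.8 CPM. Of 31 mitosis genes, 29 fell and none rose (adjusted over the list alone, 31 and 0), with a median of -1.09. Birc5 fell from 44.4 ± 4.55 to 17.7 ± 3.70 CPM and Cdk1 from 54.9 ± 7.88 to 22.8 ± 4.99 CPM. Mki67, at 377 ± 197 and 168 ± 82.1 CPM, did not pass (adjusted p = 0.0963). The camera adjusted p was 1.71e-19 for replication and 1.59e-18 for mitosis genes (adjusted p = 0.36 with an estimated correlation in both). The same Sox9-tg libraries had lower mean levels of neuronal genes, at a mean log2 CPM of 5.20 to 5.63 against 6.09 to 6.31 in control libraries.

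Some genes of neural progenitors and of neurons fell. Of 20 radial glia and neural stem cell genes, 8 fell and 2 rose (adjusted over the list alone, 12 and 2), with a median log2 fold change of -0.64. Egfr fell from 288 ± 15.1 to 50.3 ± 13.0 CPM, Gli3 from 49.0 ± 3.32 to 19.5 ± 1.65 CPM and Pax6 from 132 ± 12.7 to 63.1 ± 8.63 CPM, and the members that rose were Tspan12 and Ddah1. Both lost their calls without control replicate 1 (adjusted p = 0.107 and 0.151), control replicate 3 (0.129 and 0.18), Sox9-tg replicate 3 (0.0792 and 0.107) or Sox9-tg replicate 4 (0.0772 and 0.12), and Ddah1 also without Sox9-tg replicate 2 (0.076). Of 27 tested neuronal genes, 8 fell and 1 rose (adjusted over the list alone, 11 and 1), with a median of -0.75. Rbfox3, which encodes NeuN, fell from 41.7 ± 4.87 to 15.1 ± 2.82 CPM, and the cortical transcription factors Neurod2 (44.97 ± 19.1 to 9.32 ± 2.62 CPM) and Tbr1 (34.6 ± 18.1 to 7.18 ± 1.16 CPM) fell as well. The neuropeptide gene Npy rose from 15.2 ± 1.66 to 268 ± 100.7 CPM. Dlx1, a factor of inhibitory neurons, did not pass, at 1244 ± 360 and 723 ± 331 CPM. The camera adjusted p was 0.000105 for radial glia and 5.61e-07 for neuronal genes (adjusted p = 0.36 with an estimated correlation in both).

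Astrocyte genes split. Of 28 members, 6 fell and 3 rose (adjusted over the list alone, 13 and 3), with a median log2 fold change of -0.54. Control replicate 2 stood highest in this list, at a mean log2 CPM of 7.39 against 6.29 and 6.82 in the other control and 6.15 to 6.62 in Sox9-tg libraries, and without it the median was -0.34 (camera adjusted p = 0.036). The water channel gene Aqp4 fell from 153 ± 62.4 to 29.7 ± 6.25 CPM, and Agt, Slc1a2, Ntsr2, Glul and Gja1 fell too. S100b, which is also expressed by oligodendrocytes and Schwann cells, rose from 5.65 ± 3.59 to 112 ± 72.4 CPM, and Tril and F3 rose. With all libraries the log2 fold change of S100b was 4.27, and without control replicate 2 it was 4.88. F3 lost its call without control replicate 3 (adjusted p = 0.0615). Glul and Gja1 lost theirs without control replicate 2 (0.0678 and 0.0819), control replicate 3 (0.0975 and 0.0964) or Sox9-tg replicate 3 (0.0569 and 0.0686), and Gja1 also without Sox9-tg replicates 2 (0.0597) or 4 (0.0512). Gfap (66.6 ± 49.0 and 45.3 ± 26.6 CPM) and Slc1a3 (1386 ± 312 and 975 ± 166 CPM) did not pass. The camera adjusted p was 0.00128 (adjusted p = 0.80 with an estimated correlation), and without both libraries numbered 2 it was 0.054.

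Of 12 Hedgehog pathway genes, 5 fell and none rose (adjusted over the list alone, 5 and 0), with a median log2 fold change of -0.49 and a camera adjusted p of 0.000153 (adjusted p = 0.36 with an estimated correlation). Among these were the transcription factor genes Gli1 (36.5 ± 11.7 to 4.99 ± 1.41 CPM, -2.88, SE 0.28), Gli2 (37.1 ± 1.09 to 10.1 ± 0.580 CPM, -1.87, SE 0.11) and Gli3, with Gas1. Other signalling lists held calls in both directions and were not called by camera. In the Notch list of 22 genes, Maml2 and Notch2 rose and Dll4, Lfng and Mfng fell (adjusted over the list alone, 4 and 3; camera adjusted p = 0.613). Of 24 BMP and TGF-beta genes, 4 rose and 5 fell (adjusted over the list alone, 6 and 9; camera adjusted p = 0.513): the ligand genes Bmp4 (4.65, SE 0.65), Bmp2 (2.63, SE 0.41) and Bmp7 rose, as did Ltbp1, and Id1 (-1.41, SE 0.19), Id2, Id3, Tgfbi (-2.86, SE 0.38) and Bmpr1b fell. Without control replicate 3 the adjusted p was 0.0864 for Id2, 0.088 for Id3 and 0.098 for Bmpr1b, without control replicate 2 0.0533, 0.0986 and 0.0631, and without Sox9-tg replicate 3 0.0623, 0.106 and 0.0569. Without control replicate 2 the log2 fold change of Bmp2 was 3.24. Id2 was also lost without Sox9-tg replicate 4 (0.0512), and Id3 without Sox9-tg replicates 1 (0.0587), 2 (0.0644) or 4 (0.077). Of 24 Wnt genes, 3 rose, Wif1, Rnf43 and Fzd1, and 2 fell, Wnt5a and Notum (adjusted over the list alone, 3 and 2; camera adjusted p = 0.613). Fzd1 and Notum lost their calls without control replicate 3 (adjusted p = 0.151 and 0.115) or any of Sox9-tg replicates 1 (0.0576 and 0.0643), 2 (0.0543 and 0.0754), 3 (0.0849 and 0.113) and 4 (0.0916 and 0.0742), Fzd1 also without control replicate 1 (0.0957) and Notum without control replicate 2 (0.152). Of 22 FGF and PDGF genes, 4 rose (Pdgfra, Pdgfa, Myc and Fgfr2) and 2 fell, Il17rd and Dusp4 (adjusted over the list alone, 7 and 4). That list had a camera adjusted p of 0.0526, or 0.0094 without control replicate 2, 0.032 without control replicate 3 and 0.026 without Sox9-tg replicates 1 or 2. Il17rd and Dusp4 lost their calls without control replicate 1 (adjusted p = 0.0621 and 0.0719) or Sox9-tg replicate 3 (0.0591 and 0.116), and Dusp4 also without control replicate 3 (0.132) or Sox9-tg replicates 1 (0.0756), 2 (0.0924) or 4 (0.0933).

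Among the other Sox genes, 14 were tested, 5 rose and 2 fell (adjusted over the list alone, 5 and 2; camera adjusted p = 0.0873, or 0.037 without Sox9-tg replicate 2). Sox10, the lineage factor of oligodendrocytes, rose from 141 ± 33.2 to 758 ± 224 CPM (2.43, SE 0.29), Sox6 by 1.83, Sox13 by 0.90 and the scarce Sox14 by 3.76. Sox5, a partner of Sox9 and Sox6 in cartilage, rose from 88.8 ± 7.49 to 158 ± 37.4 CPM, a call lost without control replicate 3 (adjusted p = 0.0707). Sox11, a factor of immature neurons, fell from 1446 ± 474 to 528 ± 286 CPM, a call lost without control replicate 1 (adjusted p = 0.164), control replicate 3 (0.133), Sox9-tg replicate 2 (0.0537), Sox9-tg replicate 3 (0.123) or Sox9-tg replicate 4 (0.129). Sox7 fell at low levels (3.25 ± 2.21 to 0.552 ± 0.334 CPM) and lost its call without control replicate 2 (the log2 fold change of Sox7 moving from -2.54 to -1.83, adjusted p = 0.086), control replicate 3 (0.064) or Sox9-tg replicate 3 (0.0719). Sox8 was at 247 ± 12.8 and 246 ± 46.0 CPM. Of 35 glial transcription factor genes, 6 rose and 8 fell (adjusted over the list alone, 6 and 10; camera adjusted p = 0.459), with falls of Hes6, Lhx2, Pou3f1 and Id1. Nfia, at 276 ± 25.9 and 256 ± 60.8 CPM, did not pass.

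**Figure D2:**
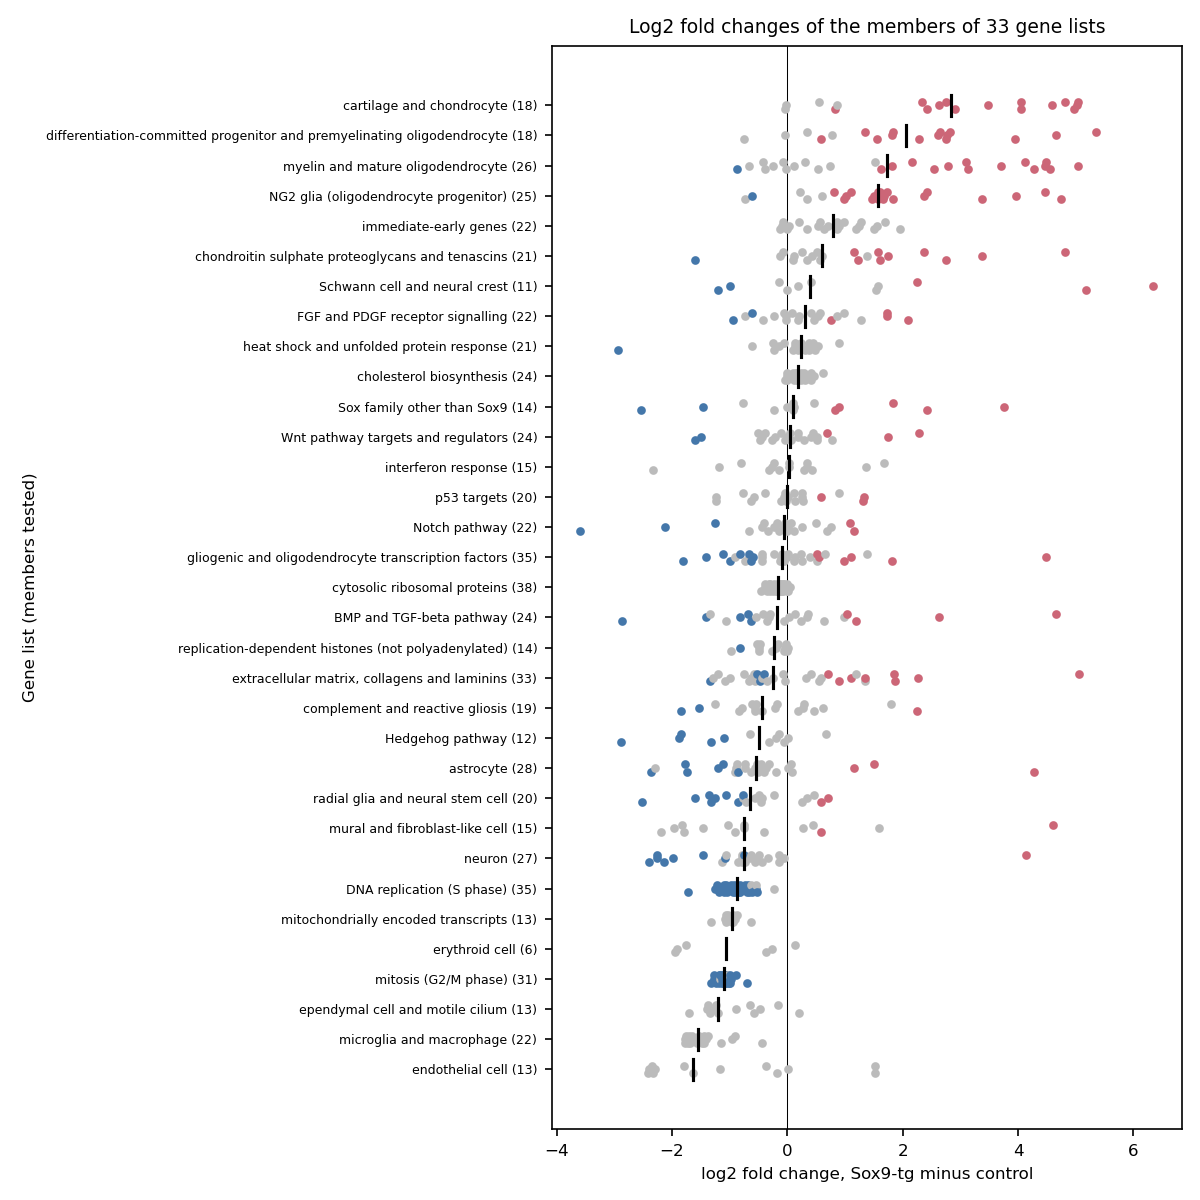
Log2 fold change (Sox9-tg minus control) of each tested member of 33 gene lists, ordered by list median (black bar), with the number tested in parentheses. Red and blue points passed adjusted p under 0.05 upward and downward, and grey points did not; 14 of 18 cartilage genes are red, and 29 of 31 mitosis genes are blue.

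Markers of other cell types were present in the preparations, with wide differences between libraries of a group. All 22 microglia genes had lower means in Sox9-tg libraries (median log2 fold change -1.54), yet none passed edgeR's test, also when adjusted over the list alone (0 and 0). At an unadjusted p under 0.05 there were 3, against 4482 of all 16616 tested genes. DESeq2 and limma-voom called 0, but 17 passed with library quality weights, a fit that called 7136 of all tested genes. Their mean log2 CPM was 2.28, 5.07 and 3.23 in control libraries and 1.13, 3.72, 2.19 and 1.77 in Sox9-tg libraries, so the groups overlapped. The camera adjusted p was 0.000313 (adjusted p = 0.80 with an estimated correlation). Without control replicate 2 the microglia median was -0.39 (camera adjusted p = 0.043), and without Sox9-tg replicate 2 it was -2.35. Endothelial genes (13 tested, median -1.64, camera adjusted p = 0.647) and ependymal genes (13 tested, median -1.20, camera adjusted p = 0.155) had no edgeR call over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 4 endothelial genes and 1 ependymal gene, DESeq2 called 1 of each and limma-voom 0, and quality weights gave 3 and 2. Endothelial genes had a camera adjusted p of 0.032 without control replicate 3, and ependymal genes 0.015 without control replicate 1, 0.0017 without control replicate 3 and 0.012 without Sox9-tg replicate 2, where the median was -2.03. Without control replicate 2 camera's direction turned upward for both, uncalled (0.077 for endothelial and 0.76 for ependymal genes, with medians of 0.50 and 0.76), as it did for endothelial genes without Sox9-tg replicate 1 (0.96). Both lists stood highest in the libraries numbered 2: endothelial genes at a mean log2 CPM of 4.41 in control replicate 2 and 3.05 in Sox9-tg replicate 2, against 1.19 to 1.74 elsewhere, and ependymal genes at 2.90 and 2.06 against -0.48 to 0.30. Of 15 mural and fibroblast genes 2 rose, Cald1 and the scarce Lum (adjusted over the list alone, 2 and 0; camera adjusted p = 0.538), and both calls were lost without control replicate 3 (adjusted p = 0.0764 and 0.069). The log2 fold change of Lum was 4.61, or 6.99 without control replicate 2 and 4.00 without Sox9-tg replicate 2. Of 6 erythroid genes edgeR called none, with 3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 4 with quality weights (adjusted over the list alone, 0 rose and 1 fell; camera adjusted p = 0.166, or 0.017 without control replicate 3). In the Schwann cell and neural crest list, 3 of 11 genes rose (Erbb3, Foxd3 and Cdh19) and 2 fell (Plp2 and Ngfr), or 4 and 2 when adjusted over the list alone (camera adjusted p = 0.151). The Cdh19 call was lost without control replicate 3 (adjusted p = 0.059), Sox9-tg replicate 2 (0.0503) or Sox9-tg replicate 3 (0.052). The Ngfr call was lost without any single library: the adjusted p was 0.189, 0.0697 and 0.082 without control replicates 1, 2 and 3, and 0.0507, 0.0925, 0.113 and 0.0705 without Sox9-tg replicates 1 to 4.

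Lists that track RNA quality, handling and metabolism held almost no called genes. The 13 mitochondrial transcripts were lower on average (median log2 fold change -0.96), with none past the gene test over all genes or adjusted over the list alone, a camera adjusted p of 0.000343 and an adjusted p = 0.75 with an estimated correlation. They took 1.53 ± 0.431% of counts in control and 0.748 ± 0.418% in Sox9-tg libraries. Ribosomal protein genes (38 tested, median -0.15) had a camera adjusted p of 0.0105 (adjusted p = 0.84 with an estimated correlation), which was 0.28 without Sox9-tg replicate 1, 0.10 without control replicate 1 and 0.054 without Sox9-tg replicate 3 (medians of -0.07, -0.09 and -0.09), while the median was -0.32 without Sox9-tg replicate 2. Immediate-early genes (22 tested, median 0.79) had a camera adjusted p of 0.0317 (adjusted p = 0.84 with an estimated correlation), which was 0.68 without control replicate 1 (median 0.36), 0.21 without Sox9-tg replicate 2, 0.066 without Sox9-tg replicate 3 and 0.07 without Sox9-tg replicate 4. Their mean log2 CPM was 3.66 in control replicate 1 and 4.85 in Sox9-tg replicate 1, against 6.30 to 7.33 elsewhere. Cholesterol synthesis genes (24 tested, median 0.18) had a camera adjusted p of 0.00621 (adjusted p = 0.80 with an estimated correlation), which was 0.17 without control replicate 3 (median 0.08), while the median was 0.36 without control replicate 2. None of these 3 lists had a member past edgeR's threshold, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 ribosomal, 1 immediate-early, 5 cholesterol and 5 mitochondrial genes. In these lists limma-voom called 0 and DESeq2 1, a cholesterol gene. Quality weights gave 7, 6, 19 and 12, in a fit that called 7136 of all 16616 tested genes. Histone genes (14 tested) had 1 fall, Hist1h1c, lost without control replicates 2 or 3 or Sox9-tg replicates 3 or 4 (adjusted p = 0.0603, 0.0873, 0.0547 and 0.0637), with the same count adjusted over the list alone and a camera adjusted p of 0.0873, which was 0.00065 without control replicate 1 and 0.0076 without Sox9-tg replicate 1.

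Camera did not call the p53, heat shock, interferon and complement lists with all 7 libraries. Of 20 p53 targets, 3 rose (Plk2, Zmat3 and Perp; adjusted over the list alone, 4 rose and 2 fell; camera adjusted p = 0.657). Plk2 rose from 45.5 ± 9.18 to 115 ± 27.7 CPM; Zmat3 lost its call without control replicate 3 (adjusted p = 0.0689), and Perp without control replicates 1 (0.131) or 3 (0.167) or Sox9-tg replicates 2 (0.0812), 3 (0.0913) or 4 (0.0799). Of 21 heat shock and unfolded protein response genes, Chac1 fell, a call lost without control replicate 3 (adjusted p = 0.227) or any of Sox9-tg replicates 1 (0.0694), 2 (0.0829), 3 (0.0782) and 4 (0.101), and when adjusted over the list alone (0 and 0). The log2 fold change of Chac1 was -2.94, or -1.12 without control replicate 3. That list had a camera adjusted p of 0.208, or 0.0063 without Sox9-tg replicate 1. Interferon genes (15 tested) had no edgeR call over all genes or adjusted over the list alone (camera adjusted p = 0.843), with 4 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom and 6 with quality weights. Of 19 complement and reactive gliosis genes, Emp1 fell from 63.6 ± 7.59 to 17.7 ± 2.67 CPM, Serping1 fell and Serpina3n rose (adjusted over the list alone, 1 rose and 4 fell; camera adjusted p = 0.127, or 0.01 without control replicate 1 and 0.038 without Sox9-tg replicate 2). The last pair of calls was lost in several fits without 1 library. Without control replicate 1 the adjusted p was 0.0987 for Serping1 and 0.118 for Serpina3n. Without control replicate 3 it was 0.0546 and 0.141, and without Sox9-tg replicate 3 it was 0.0511 and 0.0591. Without Sox9-tg replicate 4 it was 0.0621 for Serping1. The log2 fold change of Serpina3n was 2.24, or 1.52 without Sox9-tg replicate 2.

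**Figure D3:**
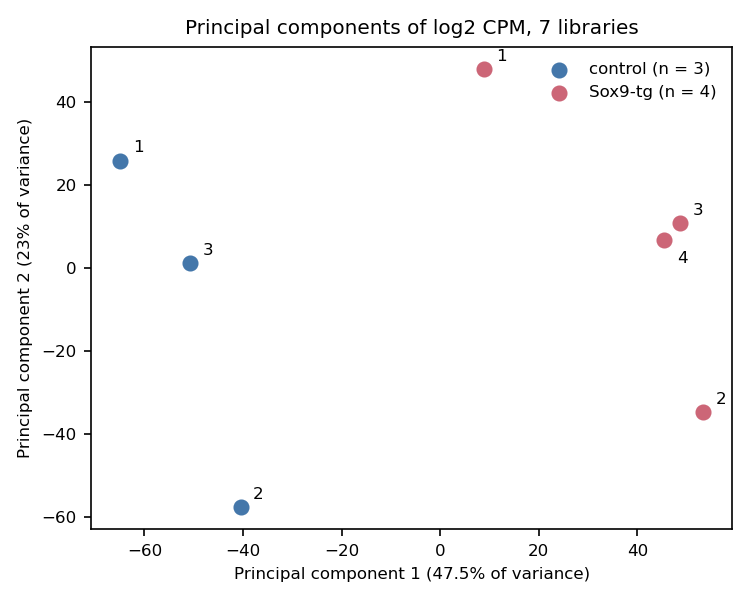
Principal components 1 and 2 of log2 CPM for 3 control (blue) and 4 Sox9-tg (red) libraries, numbered by replicate. Component 1 (47.5% of variance) separated the groups, with control libraries from -64.9 to -40.5 and Sox9-tg libraries from 8.81 to 53.3, where replicate 1 had the lowest value.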

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

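The tests of NG2 glia share, of maturing oligodendrocytes, of GC content and length and of both explanations for Sox9-tg replicate 1 were chosen only after the result was seen, whereas those of other splits of the libraries, scaling and neuronal share were chosen before. Among the 4 Sox9-tg libraries, 253 values were tested for a library far from the rest, and 13 stood apart against 12.6 by chance at 1 in 20, so they are about as many as chance gives. The control group of 3 was not tested in this way.

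Sox9-tg replicate 2 stood above the other Sox9-tg libraries in Col2a1 (1190 CPM against 597 to 632), Acan (207 against 88.6 to 95.5), Itpr2 (502 against 212 to 235), Cdh19 (6.48 against 2.88 to 3.28), Siglech (4.49 against 1.21 to 1.46), Eng (3.69 against 0.837 to 1.02) and Rps23 (267 against 151 to 161). Sox9-tg replicate 1 stood below them in Jun (697 CPM against 2120 to 2240), Egr3 (27.6 against 69.2 to 83.1) and the mean log2 CPM of NG2 glia genes (8.34 against 8.68 to 8.73), and above them in Sox5 (214 against 137 to 141). Sox9-tg replicate 4 stood above them in Dll4 (2.1 CPM against 1.55 to 1.58) and Tnc (403 against 268 to 284).

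Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave as many as 2251 changed genes. The highest other split, Sox9-tg replicates 2 to 4 against the rest, gave 1073. These counts argue against chance for the number of genes at the adjusted threshold, though 1 in 35 is the smallest share possible. At an unadjusted p under 0.05 in edgeR's test, that other split held more genes than the real one, 4658 against 4482. Splits cannot exclude a batch or cell mix that follows the groups. Chance cannot be excluded for the number of gene lists called by camera: 16 of the 35 splits gave at least the real 16 lists, and the highest other gave 21. Genes of a list vary together between libraries, and no list stayed past the threshold with an estimated correlation.

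Cartilage and oligodendrocyte-lineage genes were higher in Sox9-tg libraries. The median log2 fold change of cartilage genes exceeded that of NG2 glia genes by 1.26 (18 against 25 genes, two-sided permutation p over genes = 0.019, genes not being independent replicates). This gap passed the bound set, after the result was seen, for arguing against a larger share of NG2 glia with unchanged expression. That explanation stays open even so. A list median understates a change in share where other cells express its members. The NG2 glia genes themselves rose unevenly, Matn4 by 4.48 and Pdgfra by 1.72. GC content or transcript length was argued against as the whole cause, since 61 of 62 higher calls in the 4 lists passed after each library's trend was removed. More maturing oligodendrocytes in the Sox9-tg preparations cannot be told apart from more transcript per cell for the myelin genes (median 1.72), because bulk counts hold no count of cells. A response to Sox9 may account for the cartilage genes, as a hypothesis found and examined in the same data.

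Most cell-cycle genes and some neural progenitor and neuronal genes were lower in Sox9-tg libraries. Scaling between libraries was argued against for the cell-cycle genes, as at least 60 of 61 lower calls passed under each of 3 other scalings. GC content or length was argued against as the whole cause, since 75 of 77 lower calls in the 4 lists passed after the correction. A smaller share of neurons with unchanged expression stays open, because 16 of 27 neuronal genes (59.3%) lay within 2 SE of the list's median log2 fold change, between the bounds set for either answer. Effects of Sox9 on division or cell fate may account for the pattern but were not separated from a different mix of cells.

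Sox9-tg replicate 1 lay lower in myelin genes than the other Sox9-tg libraries. Admixture of control-like cells needs the same share of the rise in every list, but that library held a median of 0.493 of the rise in 14 cartilage genes and 0.273 in 14 myelin genes, a difference of 0.22 (two-sided permutation p over genes = 0.0084). These genes were those called higher in the same data and are not independent replicates. The p-value therefore does not measure spread between libraries. For Sox9 itself that library held 0.669 of the rise. Its Sox9 level was 70% of the mean of the other 3 (2207 CPM, the lowest other being 2741 CPM), and whether this could cause the deficit cannot be told from 1 library. The deficit that would decide was made larger after the value was seen: under the first wording, a level below every other Sox9-tg library, the value met it. Differences in age or timing of the cells were not tested.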

How the results depend on the processing

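The alternatives chosen only after the result was seen were those without both libraries numbered 2, with the GC content and length correction, and without mitochondrial genes, Gm42418 and Gm23935. None of the 2251 called genes that could be tested changed sign in any of the 22 refits. Sox9 passed in all of them, with log2 fold changes of 3.19 to 3.5, and 10 lists (NG2 glia, committed, myelin, cartilage, proteoglycans, both cell-cycle lists, radial glia, neuron and Hedgehog) passed in 21 of 22 list alternatives, all but camera with an estimated correlation, which called 0 lists. Leaving out 1 library each gave 965 to 3169 changed genes, 575 to 1785 higher, 390 to 1384 lower and 14 to 20 lists. With the Xist to Y-linked ratio as a term, 1873 genes changed (1034 higher, 839 lower), and 13 named genes lost their calls. Stricter criteria gave by construction 1292 genes (745 higher, 547 lower) with a 2-fold change, 904 (567 and 337) at an adjusted p of 0.01, and 648 lower genes with glmTreat. Library quality weights gave 7136 genes (3517 higher, 3619 lower), with weights from 0.29 to 3.65; the cause was not tested. Of 111 called genes named by the rule, 95 passed in every one of the 22 refits that tested them. Of 38 called genes named outside it, 17 did. The criteria of a 2-fold change and of an adjusted p of 0.01 were not among these refits. Of the calls lost, 15 of the first 16 and 20 of the other 21 failed without 1 library. Deviations of same-numbered libraries correlated at 0.317, 0.613 and 0.0703. Control replicates 1 and 2 each correlated best with the Sox9-tg library of the same number. Control replicate 3 correlated best with Sox9-tg replicate 1 (0.14). Whether the numbers mark a shared batch or litter cannot be told, and the main test had no term for them. The replicate block on 6 libraries gave 3086 genes (1595 higher, 1491 lower), against 1356 (826 and 530) without the block in the same 6. Signs reversed only for uncalled genes, and the cause was not tested. The log2 fold change of Sox8 was 0.0145 with no filter, 0.0331 with the Xist to Y-linked term, 0.000735 with DESeq2, 0.17 with quality weights, 0.105 without both libraries numbered 2, 0.0159 without mitochondrial genes, and -0.0948 to 0.0909 leaving out 1 library. Nfia had 0.015 without both libraries numbered 2. Leaving out 1 library gave ranges of -3.14 to 0.342 for Eng, -2.4 to 0.628 for Ak7, -0.00693 to 0.202 for Sox21, -0.0984 to 0.316 for Sox4 and -1 to 0.202 for Gfap. Depth limited scarce genes, with 3 counts worth up to 0.19 CPM.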

Other observations

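The tests of pigment-cell genes, neuronal classes and genes around Sox9 were chosen only after the result was seen, and their 4 gene lists were written after it. Several genes known from pigment cells rose. Mitf, the master regulator of melanocytes, rose from 2.74 ± 1.17 to 33.98 ± 6.31 CPM (log2 fold change 3.60, SE 0.30), Pmel by 3.42 and Dct by 3.40, and Kit and Ednrb by 1.66 and 1.497. Slc45a2 rose at low levels, a call lost without control replicate 3 (adjusted p = 0.0758), and the log2 fold change of Slc45a2 was 3.49, or 4.28 without control replicate 2, while Ptgds fell by 1.88 on the log2 scale. A general rise of pigment-cell genes is a candidate explanation: of 20 listed genes, 14 were tested, of which 7 were higher and 1 lower. As the list was written with Mitf, Pmel and Dct in view, a stricter criterion was added after that count was seen, which had met the first. Without those 3 and members of the NG2 glia list, 2 of 9 were higher and 1 lower, which leaves the explanation open. Of 19 listed neural crest and early Schwann lineage genes, 15 were tested, of which 6 were higher and 2 lower, with a median log2 fold change of 1.2. The Schwann cell and neural crest list fixed earlier, with 3 of 11 higher and 2 lower, was not called by camera (adjusted p = 0.151).

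Most listed genes of glutamatergic neurons and some genes of ventral forebrain neurons fell. Of 12 tested glutamatergic lineage genes, 10 were lower (median log2 fold change -1.87). Among them were the transcription factor genes Eomes and Neurod1 (-2.42) and the glutamate transporter gene Slc17a6 (-2.39). The glutamate transporter gene Slc17a7 (-0.62, adjusted p = 0.519) and Neurog2 (0.38, adjusted p = 0.526) did not pass and were not put through the alternatives. Of 18 ventral forebrain and interneuron genes, 12 were lower (median -1.61), among them the receptor genes Adora2a, Drd2 and Htr3a and the transcription factor gene Isl1 (-2.40). The Isl1 call was lost without control replicates 1 (adjusted p = 0.105, with the log2 fold change of Isl1 at -1.74) or 3 (0.0701) or Sox9-tg replicates 3 (0.065) or 4 (0.066). The other 6 did not pass: Dlx1, Dlx2, Dlx5 and Dlx6, core transcription factor genes of inhibitory neurons, had log2 fold changes of -0.78, -0.79, -0.56 and 0.28 (adjusted p = 0.242, 0.256, 0.425 and 0.631), Gad1 had -0.79 (0.185) and Sp8 -1.61 (0.0531). The log2 fold change of Sp8 passed without Sox9-tg replicates 1 (adjusted p = 0.0253) or 2 (0.0118). Whether a single neuronal class was lost cannot be told apart from a broader fall: the medians differed by -0.26 (two-sided permutation p over genes = 0.37), but both lists were written after falls of their members were seen, so they decide nothing.

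The long non-coding RNA gene 2610035D17Rik (GRCm38 chromosome 11, 113043895 to 113201838), 256 kb from Sox9, rose from 19.6 ± 2.03 to 208 ± 27.2 CPM (log2 fold change 3.41, SE 0.16, adjusted p = 8.78e-05), higher in all 4 Sox9-tg libraries. A rise of every gene around the locus was argued against: of the 16 other tested genes within 2 Mb, 1 was higher, Kif19a (2.21), a call lost without control replicates 1 (adjusted p = 0.0622) or 3 (0.0752), and Sstr2 (-1.92) and Sdk2 (-2.05) were lower. Without control replicate 1 the log2 fold change of Sstr2 was -1.22, and its call was lost with limma-voom (adjusted p = 0.0512). BC006965, 0.248 kb from Sox9, did not pass (1.17, adjusted p = 0.064), nor did Kcnj16, 1750 kb away (0.77, adjusted p = 0.0599). Both were higher in all 4 Sox9-tg libraries than in any control library. A rise limited to the genes closest to Sox9 was not tested. A response of 2610035D17Rik to Sox9 may account for its rise, but was not tested.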
